A study of Mus musculus with 22 samples.

How the data were processed

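RNA sequencing was done on 22 libraries of mouse TH2 cells, T helper cells grown under conditions that favour the type 2 cytokine programme. Per the labels' protocols, Balb/c mice of both sexes had been bred on diets of differing vitamin D3 content, and total RNA was taken at day 5 of polarization. Calcitriol, the hormonally active form of vitamin D, was present at 100 nM for the last 24 hours in 11 cultures, and 11 cultures received 2% ethanol as the solvent control. The labels do not say whether the calcitriol cultures held the same amount of ethanol. They also give neither the mouse, sex, diet nor culture of a single library, so none of these entered a test, and p-values measure the spread between libraries, part of which may be technical.

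Libraries were made with a stranded total RNA kit that removes globin transcripts, per the labels' protocols. The deposited table holds raw counts per Ensembl gene, one column per library, and all 22 columns were matched to samples by name. Per the submitters' processing notes, STAR 2.7.10a, HTSeq 0.13.5 and the mouse build GRCm38 were used. Their roles, the strand setting and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart with certainty, and the counts of near-identical gene copies are uncertain as well. The table lists 49671 genes, of which 22370 had no count in any library. No row lacked a gene name. Symbols, gene types and coordinates came from GENCODE release M21, which is on the same build, and 345 identifiers had no symbol there.

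The total count per library ran from 3214171 to 20258430 with a median of 7504710, a range of 6.30-fold. Genes were kept with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 11905 genes holding 99.7% of the counts of each library. Libraries were scaled with TMM factors. The main comparison was edgeR's quasi-likelihood F test with robust dispersion estimates and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are given as log2 of calcitriol over vehicle with their standard errors. Levels are given as TMM-normalised CPM (counts scaled to a common library size), as mean ± SD over 11 libraries. A fold against a group with no count was set against a floor of 3 counts over the whole group. Count intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

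There were 28 gene lists, of which 7 hold markers of other cell types. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and the rotation test fry were run as alternatives. Library measures and scores on the first 5 principal components of the 500 most variable genes were compared by two-sided permutation tests with 100000 resamples, and the smallest p these can give is 1e-05. Genes were named by a rule: the 10 largest increases and 10 largest decreases among called genes with a mean of at least 2 CPM and an established symbol; Vdr, Cyp24a1, Il4, Il5, Il13, Il10, Il2, Ifng, Gata3, Ikzf3 and Ormdl3 in every case; and up to 4 members with the smallest p in each list. Of the genes this rule names, 2 are not reported here. The groups, tests, lists, naming rule and first set of alternative settings were chosen before the data were examined.

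The alternative settings fixed in that way were DESeq2 1.42.0, limma-voom, library quality weights, other scaling factors, other filters on low counts, non-robust dispersion, up to 5 surrogate variables from sva 3.50.0, a covariate of sex-linked expression, a fold threshold of 1.2, and leaving out each library in turn. Alternatives chosen after the data had been seen were to sum libraries that were each other's best correlated partner within a group, to treat these sets as a random block, to leave out 4 libraries that stood apart on component 2, and to split the libraries at the median depth. Of the filters, the setting meant to be stricter, at least 1 CPM in 11 libraries, kept 12336 genes and so was not stricter.

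Replicates were compared before use. Over 110 pairs of libraries within groups, a chi-square test of the counts gave from 2.66 to 29.7 per degree of freedom with a median of 9.86, so no pair differed by as little as sampling noise and none was merged. The tests were tried on simulated data made from the means and library sizes of these libraries. In the simulated comparison of calcitriol with vehicle over 11734 genes, edgeR recovered 97% of genes changed by 1 on the log2 scale and 78.1% of those changed by 0.5, and 3.37% of calls were false. With no gene changed, it called 0 of 11729 genes. The simulated libraries were drawn independently, and in the first simulation 196 of the tested genes were changed. These rates therefore do not cover libraries that resemble one another in sets, nor changes in a large share of the genes.

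To look at neighbouring genes, 10747 tested protein-coding genes on the autosomes and the X chromosome were ordered by position. Rank correlations of fold changes between neighbours without overlap were compared with 1000 shuffles of the positions. In simulated fold changes over 2442 divergent pairs, the correlation was -0.0024 for independent genes, inside the shuffled range, and 0.281 where a correlation of 0.3 had been put in. Windows of 7 neighbouring genes were compared with the highest window of each shuffle. Of the possible splits of the libraries into 11 and 11, 100 were fitted, the real one included, and 20 random sets of libraries were summed. For 8 further gene families, chosen by symbol after the results were seen, calls were counted. Windows were also counted in each of the 100 splits. Figures were drawn with matplotlib 3.10.9.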

Results

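The series measured gene expression in mouse TH2 cells after 24 hours with 100 nM calcitriol, in 11 libraries, or with the ethanol vehicle, in 11 libraries, to find the genes and pathways that the hormone changes in these cells. The total count was 8626900 ± 2680020 (SD, n = 11) in the calcitriol libraries and 8575400 ± 4369380 (SD, n = 11) in the vehicle libraries, a difference smaller than the spread between libraries (permutation test, p = 0.976). The shallowest library was calcitriol replicate 2 with 3214171 counts and the deepest was vehicle replicate 10 with 20258430. Between 16330 and 20074 genes were detected per library.

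Calcitriol changed the expression of 31.5% of the genes tested. Of 11905 genes tested with edgeR, 3755 passed an adjusted p of 0.05, of which 1911 were higher and 1844 lower with calcitriol. Most changes were small, with a median absolute log2 change of 0.35 among called genes. A change of at least 1 on the log2 scale was seen for 389 genes, 221 higher and 168 lower. In 519 genes the values of the 11 calcitriol libraries did not overlap those of the 11 vehicle libraries, while chance gives 0.000284% of genes if the 22 libraries are independent. If the 6 sets of libraries that resemble one another in each group are the units, chance gives 0.216%, or 25.8 genes. The first principal component held 58.6% of the variance of the 500 most variable genes, with scores of 17.2 ± 1.24 (SD, n = 11) in calcitriol and -17.2 ± 1.40 (SD, n = 11) in vehicle libraries (permutation test, adjusted p = 5e-05, from the smallest p that the resamples can give). Scores on components 2 to 5 did not differ detectably between the groups, the lowest adjusted p being 0.981. Treatment accounted for a share of 0.995 of component 1, and components are uncorrelated by construction. These later tests therefore had almost no treatment difference left to find and say nothing further about its effect. On component 2, vehicle replicates 1 and 2 and calcitriol replicates 1 and 2 lay below the other libraries of their groups. Without these 4 libraries, an alternative added after the data were seen, 3517 genes were called. Libraries of a group also resembled one another in sets, and with each set summed to 1 sample, likewise added later, the count was 2357.

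**Figure D1:**
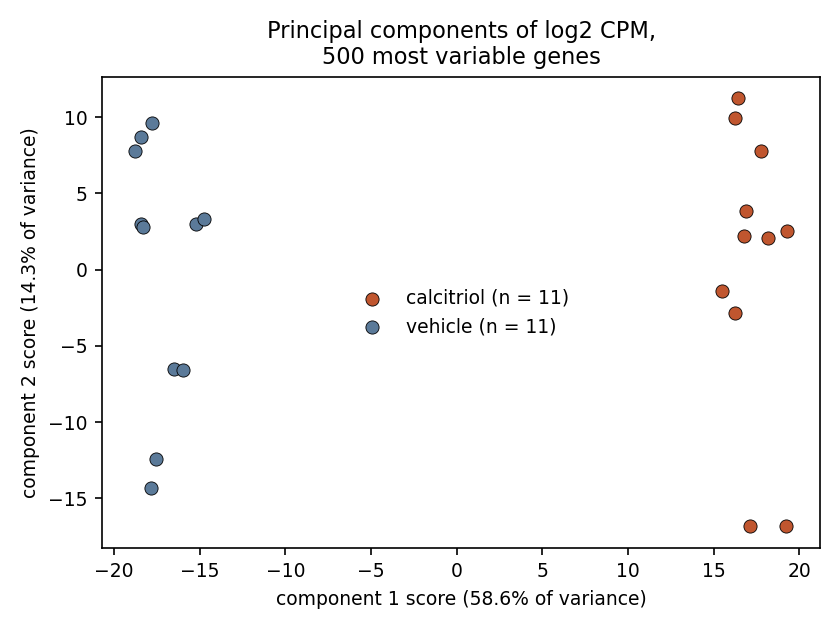
Scores of the 22 libraries on the first 2 principal components of log2 CPM over the 500 most variable genes, one point per library. The groups lie apart on component 1, which holds 58.6% of the variance, and overlap on component 2, which holds 14.3%.

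By the naming rule, with its mean of at least 2 CPM, the largest increase was in Cyp24a1 (ENSMUSG00000038567, chromosome 2, 170482708 to 170497145), the hydroxylase that inactivates calcitriol. It had 0 counts in the vehicle libraries and 2381 in the calcitriol libraries, at least 825-fold higher against a floor of 3 counts over the group, with 29.4 ± 20.2 CPM (SD, n = 11). Next came Pla2g7 (chromosome 17, 43568098 to 43612201), the phospholipase that degrades platelet-activating factor, which rose by 7.05 ± 0.22 (SE) on the log2 scale from 0.509 ± 0.325 to 62.5 ± 15.3 CPM (edgeR, adjusted p = 6.86e-18). The scavenger receptor Colec12 rose by 6.03 ± 0.33, and the inducible cyclooxygenase Ptgs2 rose by 5.34 ± 0.21 to 29.6 ± 7.78 CPM. Serpinb2, Parm1, Nt5c1a and Akap6 rose by between 4.29 and 4.93, and Fgg went from 0.284 ± 0.270 to 6.25 ± 6.22 CPM. The epidermal growth factor receptor ligand Areg rose by 4.05 ± 0.24, from 3.12 ± 1.05 to 49.6 ± 20.2 CPM. All 11 calcitriol libraries lay above every vehicle library for each of these 10 genes.

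By the naming rule, with its mean of at least 2 CPM, the largest decrease was in the desmosome gene Dsp. Its log2 change was -3.61 ± 0.22 (SE), from 7.46 ± 1.87 to 0.548 ± 0.317 CPM (edgeR, adjusted p = 5.17e-13). The neuropeptide genes Grp and Spx followed at -3.22 ± 0.44 and -3.17 ± 0.46. Among cytokine and ligand genes, Il3 changed by -3.00 ± 0.57, Fasl by -2.96 ± 0.39, Il2 by -2.78 ± 0.23 and Il22 by -2.44 ± 0.55. Il2, the T cell growth factor, went from 4.98 ± 1.70 to 0.718 ± 0.272 CPM, and all 11 calcitriol libraries lay below every vehicle library. For Il22 this held for 6 of 11 calcitriol libraries, and for Il3 and Fasl for 9. Ramp3, Syn2 and Bst1 complete the 10 largest decreases, at -2.60, -2.54 and -2.36.

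**Figure D2:**
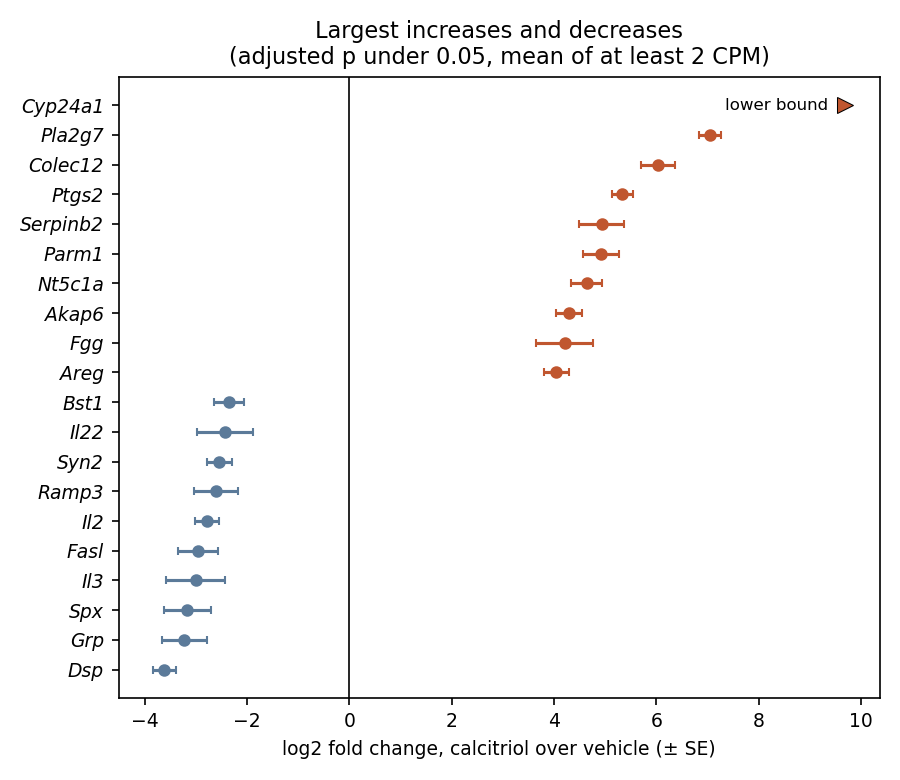
Log2 fold change of calcitriol over vehicle for the 10 largest increases and 10 largest decreases by the naming rule, with bars of 1 SE (n = 11 per group). The arrowhead for Cyp24a1 marks its lower bound of 825-fold, since no vehicle library had a count.

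Among the receptor, metabolism and classical target genes of vitamin D, 4 of 16 measured members rose and 6 fell. Adjusted over the list alone, 5 rose and 6 fell. Apart from Cyp24a1, the plasma membrane calcium pump Atp2b1 rose from 218 ± 19.2 to 338 ± 34.1 CPM (log2 change 0.63 ± 0.06). Transcripts of the receptor itself, Vdr (chromosome 15, 97854425 to 97910630), fell from 16.1 ± 5.70 to 5.40 ± 4.50 CPM, with a log2 change of -1.73 ± 0.31 (edgeR, adjusted p = 0.000122). The osteoclast differentiation factor Tnfsf11, a calcitriol target in bone, changed by -2.06 ± 0.15, and Dhcr7, which draws the precursor 7-dehydrocholesterol into cholesterol, by -0.83 ± 0.11. In the libraries that stood apart on component 2, Cyp24a1 reached 62.7 and 75.7 CPM, against 16.6 to 27.0 in the other 9 calcitriol libraries. Vdr was higher in replicates 1 and 2 of both groups, at 24.6 and 28.0 CPM against 7.20 to 16.8 in vehicle and at 11.3 and 16.4 against 1.86 to 5.76 in calcitriol libraries. The median log2 change of the list was -0.07 and its mean 0.23 with Cyp24a1 at its bound, and the direction was down by camera (adjusted p = 0.607) and up by fry (0.435).

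The signature type 2 cytokines did not move together. Il4 was at 86.8 ± 8.00 CPM in vehicle and 96.7 ± 17.8 in calcitriol libraries (log2 change 0.15 ± 0.08, edgeR adjusted p = 0.166), and Il5 at 44.6 ± 22.4 and 62.5 ± 21.1 (0.49 ± 0.25, adjusted p = 0.147). Il13 fell from 333 ± 104 to 203 ± 106 CPM (-0.72 ± 0.23, adjusted p = 0.0204). Vehicle replicates 1 and 2 and calcitriol replicates 1 and 2 held the highest Il13 values of their groups, at 491 and 522 and at 408 and 421 CPM. The Il13 call was lost with the sets of libraries summed (-0.73, adjusted p = 0.0926), in a fit that treats the sets of both groups as unrelated. This was the highest over 29 alternatives, and the lowest was 2.53e-07, with surrogate variables. Il5 passed the threshold with limma-voom, surrogate variables, without vehicle replicate 2 or without the 4 libraries apart on component 2, with adjusted p = 0.0459, 0.000915, 0.0420 and 0.0349, and the highest over its alternatives was 0.255. Il10, an anti-inflammatory cytokine, rose from 191 ± 51.2 to 521 ± 39.5 CPM (1.45 ± 0.11, adjusted p = 4.81e-10), in 11 of 11 calcitriol libraries above every vehicle library. Of the 11 measured cytokine and chemokine genes of the type 2 list, 2 rose, Il10 and Areg, and 5 fell, Il13, Il9, Il3, Tnfsf11 and Csf2, with the same numbers adjusted over the list alone. Csf2 is named here after its value was seen. Il9, the mast cell growth factor, changed by -1.89 ± 0.23. Camera gave no call (adjusted p = 0.606).

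**Figure D3:**
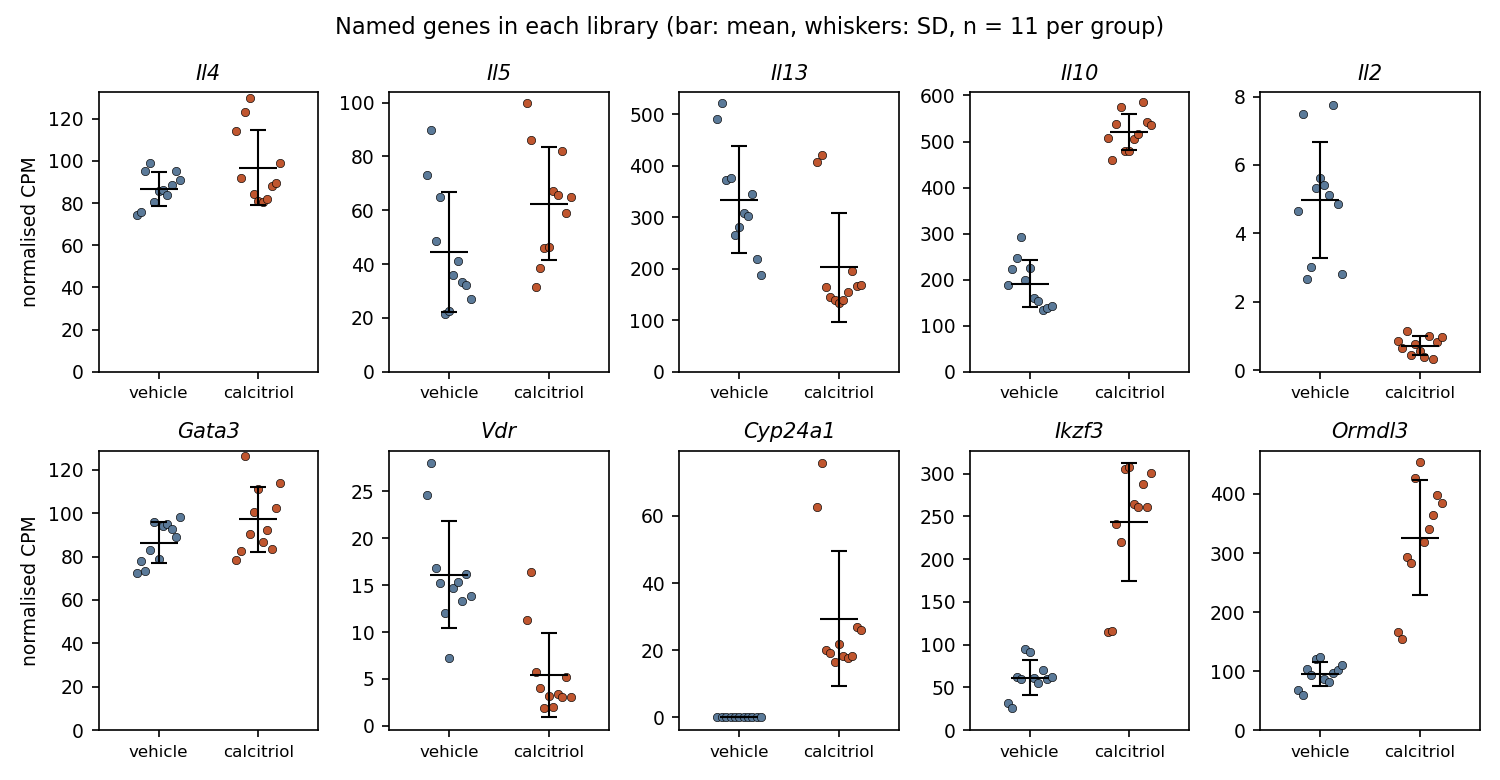
Normalised CPM of 10 named genes in each library, with the group mean as a bar and the SD as whiskers (n = 11 per group). Il10, Cyp24a1, Ikzf3 and Ormdl3 lie higher in all 11 calcitriol libraries, Il2 lies lower, and the values of Il4, Il5 and Gata3 overlap between the groups.

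Of the Th2 regulators and receptors, 9 of 22 rose and 5 fell, and adjusted over the list alone 12 rose and 6 fell. Gata3, the lineage-defining transcription factor, was at 86.5 ± 9.56 and 97.2 ± 15.1 CPM (log2 change 0.17 ± 0.08, edgeR adjusted p = 0.0967). It passed the threshold only with surrogate variables (adjusted p = 0.0243) and without calcitriol replicate 1 (0.0461), and the highest value over 29 alternatives was 0.310. Maf, an activator of the Il4 gene, rose by 0.88 ± 0.07, Ets1 by 0.68 ± 0.06 and Ikzf1, which encodes Ikaros, by 0.44 ± 0.04. Bhlhe40, a repressor of Il10, changed by -1.51 ± 0.12. The list was higher by fry (adjusted p = 0.00117), and camera gave adjusted p = 0.197, or adjusted p = 0.813 with an estimated correlation.

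Genes of Th1 and cytotoxic cells more often fell, with 9 of 18 lower and 4 higher, also when adjusted over the list alone. Tbx21, the Th1 master regulator, changed by -1.26 ± 0.11 from 8.12 ± 1.27 to 3.39 ± 0.522 CPM, and Tnf by -1.31 ± 0.13. The interferon gamma receptor Ifngr1 rose by 0.51 ± 0.06. Ifng itself had 8 counts over all vehicle and 12 over all calcitriol libraries, a ratio of 1.56 with a counting interval of 0.586 to 4.40, and was below the filter. Fry gave adjusted p = 0.00791 for a fall of the list, and camera 0.249. In the Th17 list, 3 of 8 genes fell and 1 rose, with the same numbers over the list alone. Il1r1 changed by -1.67 ± 0.25 and Il22 by -2.44 ± 0.55, while Il6ra rose by 0.26 ± 0.07. The median log2 change of this list was 0.00 and its mean -0.54, and neither camera (adjusted p = 0.590) nor fry (0.142) called it.

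Regulatory T cell and inhibitory receptor genes went both ways, with 7 of 22 higher and 10 lower, also over the list alone. Ctla4, an inhibitory receptor, rose from 609 ± 114 to 1439 ± 129 CPM (1.24 ± 0.09). Prdm1, which encodes Blimp-1, rose by 1.61 ± 0.14 and Il2ra, the high-affinity IL-2 receptor chain, by 0.45 ± 0.04. The median log2 change of the list was -0.17 and its mean 0.08, fry gave adjusted p = 0.0262 for an increase, and camera did not call it (0.799). Of follicular helper genes, 2 of 9 rose and 5 fell, and over the list alone 3 rose and 5 fell. The transcriptional coactivator Pou2af1 rose by 1.71 ± 0.16, and Id3, Tcf7 and Slamf6 changed by -0.74 ± 0.18, -0.67 ± 0.16 and -0.51 ± 0.13. Fry called the list lower (adjusted p = 0.0262) and camera did not (0.590).

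In the IL-2 and STAT5 list 6 of 22 genes rose and 6 fell, and over the list alone 7 rose and 7 fell. Beside Il2, the survival gene Bcl2l1 was lower, at -0.68 ± 0.09, whereas Il2ra and the common cytokine receptor chain Il2rg were higher, the latter by 0.65 ± 0.04. Camera gave adjusted p = 0.781 and fry 0.790. Of T cell receptor and early activation genes, 4 of 28 rose and 11 fell, and over the list alone 5 rose and 12 fell. The NF-kB subunit Rel changed by -0.98 ± 0.11, the phosphatase Dusp4 by -0.64 ± 0.09 and Ier2 by -0.43 ± 0.08, and Tnfaip3, an inhibitor of NF-kB signalling, rose by 0.75 ± 0.11. Of naive, memory and homing genes, 11 of 23 rose and 5 fell, with the same numbers over the list alone. The integrin chain Itgal rose by 0.69 ± 0.07, the chromatin organiser Satb1 by 0.49 ± 0.05 and the chemokine receptor Ccr2 by 1.09 ± 0.17, and Itgb1 changed by -0.30 ± 0.05. Fry called the activation list lower (adjusted p = 0.00791) and the homing list higher (0.00628), and camera gave adjusted p = 0.197 for both, with adjusted p = 0.813 for both at an estimated correlation.

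**Figure D4:**
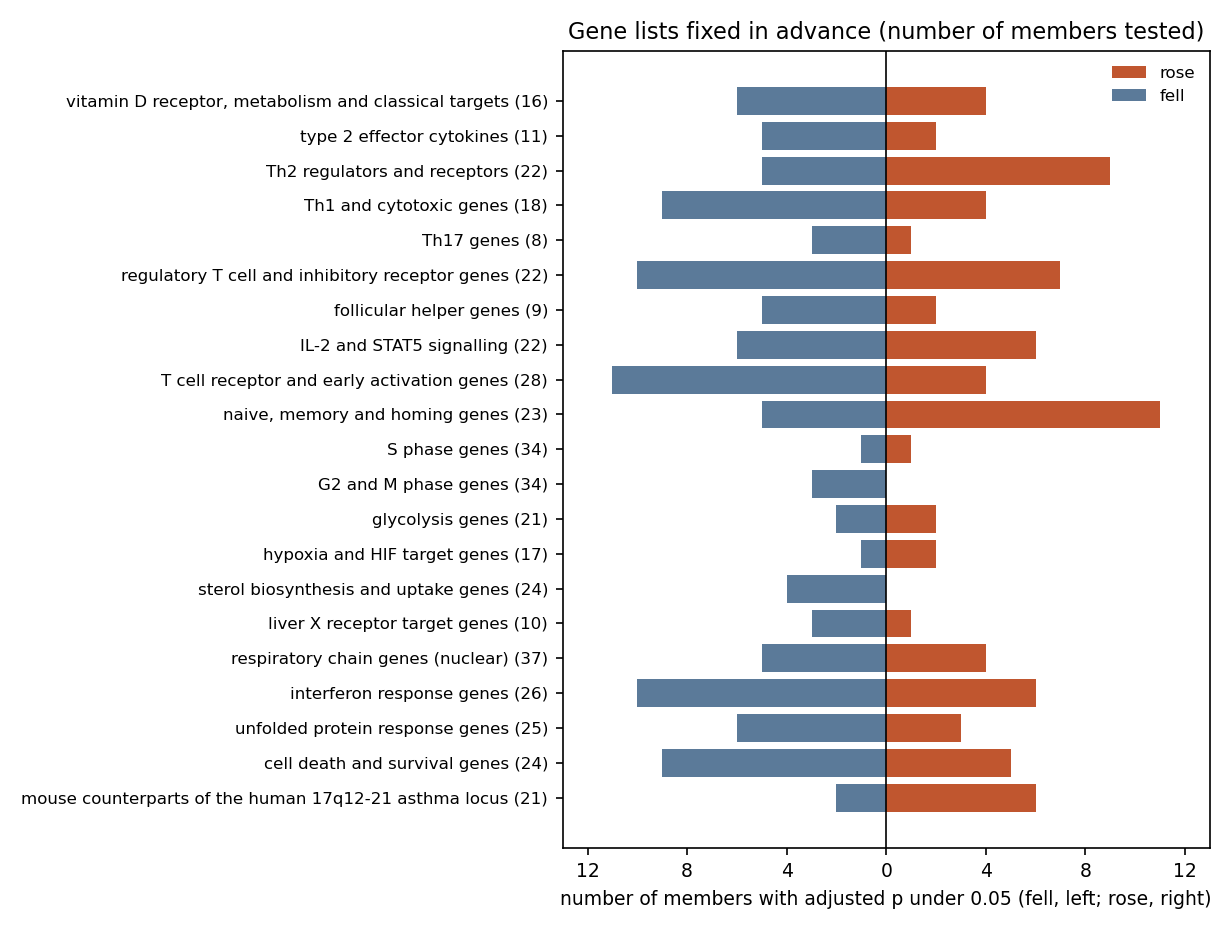
Number of members of 21 gene lists that rose (right of 0) or fell (left of 0) at an adjusted p under 0.05, with the number of members tested in brackets. Of the S phase list 1 gene rose and 1 fell among 34, and of the activation list 4 rose and 11 fell among 28.

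Proliferation and energy metabolism genes were mostly not called. Of 34 S phase genes 1 rose, Rfc3, and 1 fell, Gins2 at -0.30 ± 0.07, and only Gins2 passed when adjusted over the list alone. The Rfc3 call, at 0.20 ± 0.07, was lost when any of 7 single libraries was left out (adjusted p = 0.0505 to 0.0739). Of 34 G2 and M phase genes 3 fell, Kif23, Cdca8 and Ttk, by no more than 0.23 on the log2 scale, and 0 passed over the list alone. The calls of Cdca8 and Ttk were lost when any of 9 and any of 15 single libraries was left out, at adjusted p of up to 0.0620 and 0.0867, and the calls of Rfc3 and of all 3 of these genes were lost with the sets summed, with log2 changes of 0.21 for Rfc3, -0.23 for Kif23, -0.21 for Cdca8 and -0.18 for Ttk. Top2a had 1077 ± 93.4 and 993 ± 113 CPM (adjusted p = 0.146). It passed only with surrogate variables (log2 change -0.12, adjusted p = 0.000922), a fit in which 0 named genes lost a call. In glycolysis, 2 of 21 genes rose and 2 fell, and over the list alone 1 rose and 2 fell. The calls of Pgk1 and Slc16a1 were lost with the sets summed, at log2 changes of 0.17 and -0.17 against 0.16 and -0.17, and that of Pgk1 also when any of 15 single libraries was left out (adjusted p = 0.0513 to 0.0928). Hk2, the inducible hexokinase, changed by -0.74 ± 0.07 from 372 ± 38.7 to 223 ± 29.0 CPM, and Pfkfb3, which makes an activator of phosphofructokinase, rose by 0.66 ± 0.09. Of 17 hypoxia genes 2 rose and 1 fell, also over the list alone, and these calls, for Hif1a, Bnip3l and Vegfa, were lost with the sets summed, where the log2 changes were 0.31, 0.36 and -0.33 against 0.30, 0.36 and -0.33 over all libraries. The Bnip3l call was also lost without calcitriol replicate 3 or 4 or vehicle replicate 9 (adjusted p = 0.0524, 0.0570 and 0.0519). Of 37 nuclear genes of the respiratory chain 4 rose and 5 fell, also over the list alone, among them Ndufa1 at 0.48 ± 0.05 and Atp5b at -0.27 ± 0.04. Camera adjusted p for these 5 lists ran from 0.201 to 0.999, and fry called 0 of them. The median and mean log2 changes of glycolysis genes were -0.04 and 0.00, with camera up and fry down, and those of hypoxia genes 0.00 and -0.02.

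Of 24 sterol synthesis and uptake genes 4 fell and 0 rose, also over the list alone. Dhcr7 is described above, and Pmvk, Hsd17b7 and Stard4 changed by -0.39 ± 0.07, -0.38 ± 0.07 and -0.20 ± 0.06, the call of Stard4 being lost with the sets summed at -0.19. Camera gave adjusted p = 0.123 for this list and adjusted p = 0.888 with an estimated correlation. The list passed with surrogate variables (adjusted p = 0.0374) and without vehicle replicate 3 or 4 or calcitriol replicate 5, 6 or 9 (0.0355, 0.0422, 0.0413, 0.0413 and 0.0428). Of 10 liver X receptor targets 1 rose, the phospholipid enzyme Lpcat3 by 0.69 ± 0.07, and 3 fell, Scd1 at -0.67 ± 0.07, Abca1 at -0.73 ± 0.12 and Scd2 at -0.11 ± 0.04, with the same numbers over the list alone (camera, adjusted p = 0.590). The Scd2 call was lost with the sets summed, at -0.11, and when any of 6 single libraries was left out, namely calcitriol replicates 1 and 2 and vehicle replicates 7, 8, 10 and 11 (adjusted p = 0.0517 to 0.0587).

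Interferon response genes split. Of 26 measured members 6 rose and 10 fell, and over the list alone 7 rose and 10 fell. The antiviral gene Oas3 changed by -1.63 ± 0.12 from 36.4 ± 7.65 to 11.9 ± 2.82 CPM, and Ifi27 by -1.26 ± 0.09. The guanylate-binding proteins Gbp3 and Gbp7 rose by 1.02 ± 0.10 and 0.69 ± 0.06. Camera gave adjusted p = 0.590. In the unfolded protein response list 3 of 25 rose and 6 fell, and over the list alone 3 rose and 8 fell. The stress-induced factor Atf3 changed by -1.07 ± 0.13, Trib3 by -0.73 ± 0.13 and Asns, asparagine synthetase, by -0.58 ± 0.09, and Xbp1 rose by 0.29 ± 0.06. Fry gave adjusted p = 0.0369 for a fall and camera 0.423. Of 24 cell death and survival genes 5 rose and 9 fell, and over the list alone 6 rose and 9 fell. The pro-apoptotic gene Bcl2l11 rose by 1.12 ± 0.11, while Gadd45b, Bcl2l1 and Fasl changed by -1.13 ± 0.08, -0.68 ± 0.09 and -2.96 ± 0.39. Fry called this list lower (adjusted p = 1.8e-05), and camera gave 0.436.

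Genes of the mouse region that corresponds to a human asthma-associated locus rose around Ikzf3 and Ormdl3 on chromosome 11. Ikzf3 (98464902 to 98546031), which encodes the lymphoid factor Aiolos, rose from 61.4 ± 20.7 to 244 ± 69.1 CPM (log2 change 2.00 ± 0.21, edgeR adjusted p = 1.42e-07). Its neighbours Zpbp2 (98551097 to 98558665) and Ormdl3 (98581256 to 98587368), a regulator of sphingolipid synthesis, rose by 2.25 ± 0.21 and 1.78 ± 0.17, the latter to 326 ± 97.3 CPM. All 11 calcitriol libraries lay above every vehicle library for Ikzf3 and Ormdl3, and 10 of 11 for Zpbp2. Mien1, on the other side of Ikzf3, rose by 0.44 ± 0.06. In the list of the region 6 of 21 measured genes rose and 2 fell, and over the list alone 9 rose and 3 fell (fry adjusted p = 0.000127, camera 0.197, and 0.813 with an estimated correlation). Psmd3, the next tested gene beyond Ormdl3, had a log2 change of 0.03 ± 0.06. Of genes between them that were below the filter, named here after their counts were seen, Lrrc3c had 9 counts over the vehicle and 119 over the calcitriol libraries, Gsdma 33 and 181, and Gsdma3 0 and 18. Replicates 1 and 2 of both groups were lower than the other libraries of their group. Ikzf3 was at 26.3 and 31.9 CPM against 55.2 to 94.8 in vehicle and at 115 and 116 against 220 to 308 in calcitriol libraries, and Ormdl3 at 59.5 and 67.9 against 81.4 to 124 and at 155 and 166 against 283 to 454.

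**Figure D5:**
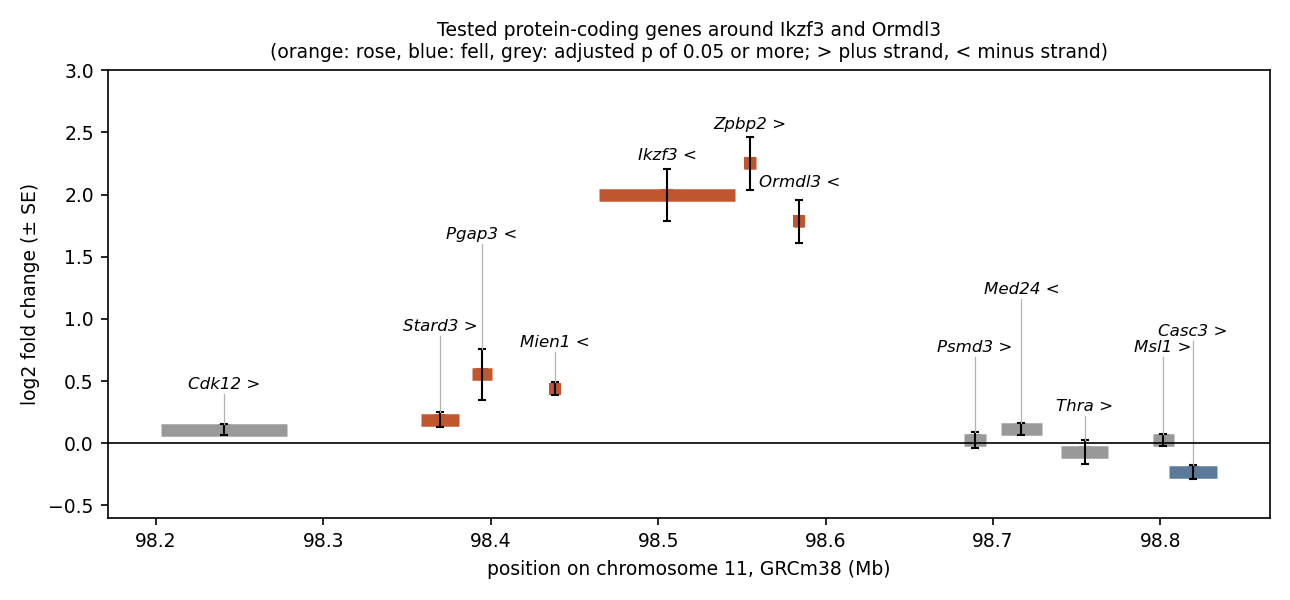
Log2 fold change (± SE) of tested protein-coding genes around Ikzf3 and Ormdl3 on chromosome 11 of GRCm38, each drawn as a bar along its annotated span. Ikzf3, Zpbp2 and Ormdl3 rose by 1.78 to 2.25, and Psmd3 and Thra beyond them were not called.

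Over all 28 lists, camera called 0 at an adjusted p of 0.05 and 7 at an unadjusted p of 0.05. With an estimated correlation the numbers were 0 and 1. Fry, which asks whether the genes of a list move one way and not whether they differ from other genes, called 13 lists, and 22 by its test for change in either direction.

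Few markers of other cell types passed the filter on low counts. Of B cell markers 3 were measured and 0 called, with Cd79b at 2.21 ± 0.777 and 1.90 ± 0.701 CPM. Ighm had a log2 change of 0.29 ± 0.19, and Ebf1 was at 4.54 ± 2.10 and 7.08 ± 3.61 CPM (edgeR, adjusted p = 0.0946). Ebf1 passed as higher with surrogate variables (8.05e-06) and without the 4 libraries apart on component 2 (0.0410). It also passed without vehicle replicate 2 (0.0439) or calcitriol replicate 9 (0.0493), and its highest value over the alternatives was 0.287. The macrophage list had 1 measured gene, Cd68, at 6.02 ± 1.64 and 8.12 ± 2.52 CPM (edgeR, adjusted p = 0.0541), which passed over the list alone. Over all genes Cd68 passed as higher with DESeq2 (0.0498), limma-voom (0.0473) and surrogate variables (0.000822). It also passed without the 4 libraries apart on component 2 (0.0369). The same held without vehicle replicate 1, 2 or 3 or calcitriol replicate 7, 8, 9 or 11 (0.0284 to 0.0465). Its highest value over the alternatives was 0.177. Of 2 measured CD8, NK and gamma delta genes 0 were called, and Cd8b1 was at 5.98 ± 1.14 and 5.65 ± 1.89 CPM. Of 8 dendritic cell genes 2 rose, H2-Eb1 to 2.27 ± 0.959 CPM and Cd86 to 2.19 ± 0.756. Another 2 fell, Zbtb46 and Bst2, the latter from 33.2 ± 6.67 to 20.9 ± 3.13 CPM, with the same numbers over the list alone. The list had a median log2 change of -0.05 and a mean of 0.00 (fry adjusted p = 0.0411 for a fall, camera 0.753). The H2-Eb1 call was lost with the sets summed, at 0.83 against 0.82, and the Cd86 call without the 4 libraries apart on component 2, at 0.68 against 0.90. Ly6g, the 1 measured granulocyte gene, rose from 0.191 ± 0.128 to 2.16 ± 0.571 CPM (camera adjusted p = 0.0675, fry 1.08e-10). Camera passed without vehicle replicate 3, 4 or 8 or calcitriol replicate 5, 6 or 9 (0.0355 to 0.0496). There was also a rise of Itga2b, the 1 measured platelet gene, from 4.63 ± 1.21 to 7.10 ± 1.28 (camera 0.340, fry 0.00168). Of 3 fibroblast, epithelial and endothelial markers Epcam and Pecam1 rose, by 1.19 ± 0.15 and 0.84 ± 0.10. Epcam went from 9.74 ± 3.28 to 22.2 ± 4.99 CPM and Pecam1 from 38.3 ± 7.46 to 68.9 ± 11.2 CPM. Krt18 was not called over all genes but passed over the list alone as lower. For this list camera gave adjusted p = 0.197 and fry 9.43e-05.

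The makeup of the libraries differed in 1 of 8 measures. Haemoglobin and Y-linked genes were among these measures but almost absent from every library, so their tests could hardly find a difference. The 50 most abundant genes took 22.2% ± 0.944 (SD, n = 11) of the counts with calcitriol and 20.6% ± 0.601 (SD, n = 11) with vehicle (permutation test, adjusted p = 0.00232). Mitochondrial genes took 2.28% ± 0.392 and 2.32% ± 0.444, and histone genes 0.984% ± 0.216 and 0.987% ± 0.205. Although mice of both sexes are named in the protocols, Y-linked genes had 3 counts over all 22 libraries, with 0 counts in 19 of them, and Xist lay between 207 and 319 CPM in each library.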

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

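The summed sets, the random block, the fits without 4 libraries and the split by depth were chosen after seeing the data. DESeq2 called 810 genes with a change of at least 1 on the log2 scale and the fit with no low count filter 946, where the reported count was 389, and both tested 27301 genes. Surrogate variables raised the higher genes to 2644, the lower genes to 2893 and the called lists to 1, and the cause was not tested. A fold threshold of 1.2 asks for more and left 1166 genes, 631 higher and 535 lower. Fry called 13 lists, since it tests another hypothesis than camera. With libraries summed by set, 6 samples per group, 2357 genes were called, 1242 higher and 1115 lower, of which 2239 were among the 3755 and 0 of these had the opposite direction. With 6 vehicle and 5 calcitriol libraries up to the median depth, 1766 genes were called, 1002 higher and 764 lower, and with the 11 deeper libraries 3329. Depth cannot be named as the cause, since the 4 libraries apart on component 2 were all among the shallower ones. Leaving out 1 library at a time gave from 3467 called genes (without calcitriol replicate 10) to 3806 (without calcitriol replicate 9), and from 0 to 2 called lists. The 2 were the sterol and granulocyte lists, without vehicle replicate 3 or 4 or calcitriol replicate 5, 6 or 9, and without vehicle replicate 8 the granulocyte list alone. All other settings gave from 2713 (sets as a random block) to 5537 called genes (surrogate variables). The share of component 1 that followed treatment was 0.995, and 0.993 with 2000 genes. Over 29 alternatives for each of 114 named genes, 3184 of 3306 results kept direction and side of the threshold, 0 called values changed sign, and 90 genes kept both in each alternative. Of the 3184, 2433 came from fits that left out 1 library and so shared nearly all data with the main fit. Most named genes were also chosen for a small p or a large change, which favours a high share. With the sets summed, 14 named genes lost their call. The covariate of sex-linked expression set Y-linked genes against Xist. It therefore followed Xist and single Y-linked reads, of which there were 3 over all libraries. No paired analysis was run because the labels give no number, animal or culture that pairs libraries. Surrogate variables were used for variation that both groups share. The sets found within each group held the same replicate numbers in both groups, but these numbers only follow the order of the samples. Neither the summed fit nor the random block matched sets across groups, so any variation that both groups share stayed in their spread.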

Other observations

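The test of duplicate libraries, the random sets and the tests of non-coding direction were chosen only after the results were seen. So were the gene families and genes of the next paragraphs, for which counts and values are therefore given without a test of the family.

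Of 11 measured NF-kB subunits and inhibitors 2 rose and 7 fell with calcitriol, among them Rel at -0.98 ± 0.11 (SE), Nfkb2 at -0.97 ± 0.06, Nfkbie at -0.71 ± 0.06 and Relb at -0.53 ± 0.07. Without Rel, named in the report, 2 of 10 rose and 6 fell. Of 13 TNF superfamily ligands 6 fell and 0 rose, among them Fasl at -2.96 ± 0.39, Lta at -2.13 ± 0.27, Tnfsf11 at -2.06 ± 0.15 and Tnf at -1.31 ± 0.13. Without Fasl, Tnfsf11 and Tnf, named in the report, 3 of 10 ligands fell, where 31.5% of all tested genes were called. The TNF receptors went both ways, with 7 of 18 higher and 5 lower, and the decoy receptor genes Tnfrsf23 and Tnfrsf22 rose by 2.47 ± 0.16 and 1.67 ± 0.12.

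Beside Pla2g7 and Ptgs2, the cytosolic phospholipase Pla2g4a rose by 2.47 ± 0.12 and the prostaglandin E synthase Ptges by 2.36 ± 0.27. Of the 10 measured phospholipase A2, cyclooxygenase and eicosanoid enzymes other than Pla2g7 and Ptgs2, 4 rose and 3 fell. Of 13 retinoid genes 6 fell and 1 rose. The retinaldehyde dehydrogenase Aldh1a3 changed by -3.36 ± 0.39, the retinol transporter Stra6 by -2.11 ± 0.24 and Crabp2 by -1.74 ± 0.14, and the retinaldehyde reductase Dhrs3 rose (edgeR, adjusted p = 7.96e-09). Of the 7 guanylate-binding proteins other than Gbp3 and Gbp7, 4 rose and 1 fell. Polyamine genes went both ways, 3 higher and 3 lower of 10, as did sialyl- and glycosyltransferases, 7 higher and 5 lower of 23. Of the latter, St3gal5, which makes the ganglioside GM3, rose by 2.24 ± 0.12.

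The number of called genes was compared over splits of the 22 libraries. Only 1 of 100 splits, the real one, gave 3755 or more, and the highest of the others was 1259. For changes of at least 1 on the log2 scale the real split gave 389 and the highest other 114, and for lists called by fry 13 and 4, again with 1 of 100 splits as high. The split with 1259 held 9 of 11 libraries of a treatment group on one side, and 96 of the 99 other splits called 0 genes. The splits moved single libraries and so broke up the sets that resemble one another. Splits that mix the groups also hold the treatment difference as spread within each side. The counts argue against chance division only if single libraries are independent, and do not exclude it with the sets as units.

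Neighbouring genes changed alike. Over 2442 pairs of divergent neighbours without overlap, which are transcribed away from each other, log2 changes had a rank correlation of 0.180, above the highest of 1000 shuffles at 0.0594, which argues against read-through. It was 0.171 without pairs whose symbols share a stem and 0.179 after removal of a trend on GC content and length (highest shuffles 0.0604 and 0.0581), which argues against gene copies and composition. The other 99 splits of the libraries, however, gave from 0.0270 to 0.257 with a median of 0.115, and 6 of them reached the value for treatment, so the size of the correlation is not specific to calcitriol. By distance, the treatment value was 0.276 for 829 divergent pairs up to 10 kb apart, 0.138 at 10 to 50 kb and 0.179 at 50 to 200 kb. These lay above their highest shuffles, at 0.0945, 0.125 and 0.145. Over 200 kb the 403 divergent pairs gave 0.0897, inside the shuffled range of up to 0.173. A candidate explanation left open is that neighbours share regulation in these cells whatever separates the libraries, for which no biological test was run.

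Of windows of 7 neighbouring genes, 14 passed a family-wise threshold of 0.05 against shuffled positions. As many or more did so in 6 of 100 splits of the libraries, the real one included, with 31 in the highest of the others. Chance division of the libraries is therefore not excluded, and no region found by windows is reported as a response to calcitriol. None of the 14 windows held Ikzf3 or Ormdl3, whose rise rests on the tests of single genes.

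Libraries of a group resembled one another in sets. The most alike pair differed by a chi-square of 2.66 per degree of freedom, where sampling noise alone gives about 1, which argues against a library deposited more than once. With each set summed to 1 sample 2357 genes were called, while random sets of the same sizes gave from 2920 to 4205 in 20 draws, so fewer samples alone do not account for the lower count. This is in line with libraries that share an animal or culture, but a fit with surrogate variables called 5537, so whether 3755 is too high or too low for independent samples stays open. Diet, which the labels name but do not assign, stays open as a biological source of the sets and was not tested, whereas no library showed male expression, with 3 Y-linked counts over all 22 and Xist at 207 CPM or more in each.

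Among genes annotated as non-coding RNA, with pseudogenes and receptor segments left out, 101 rose and 34 fell of 135 called. Fisher's exact test of direction against protein-coding genes gave p = 6.14e-09 (two-sided). It treats genes as independent and was chosen after the direction was seen. The direction was not compared with other splits of the libraries, so this p does not measure chance over libraries. The share of rises was 74.8%, against a 95% range of 34.8% to 51.9% over 1000 draws of called coding genes matched on abundance, which argues against low expression as the source. Among the 63 that overlap no coding gene 71.4% rose. Whether non-coding RNA was made more or degraded less stays open and was not tested.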
